A study of Rattus norvegicus with 4 samples.

How the data were processed

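The series holds 4 samples of rat soleus, 1 per group: normal, regenerated, overloaded and regenerated overloaded muscle. Per the labels, RNA of 6 muscles per group was mixed in equal amounts, total RNA was extracted with Isogen, and Cy3-labelled cRNA was made with the Low Input Quick Amp kit and hybridised to Agilent arrays. The 4 arrays lay on 1 slide, normal and regenerated in row 1 (columns 3 and 4) and the overloaded groups in row 2 (columns 1 and 2), so slide row and age go with overload.

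The deposited scanner files give, for every spot, the processed signal as a fluorescence intensity (background-subtracted and spatially detrended by the scanner software, not scaled between arrays), the median signal and the median local background as intensities, and flags (other) for spots well above background, saturated or outlying. The file headers name Feature Extraction 11.5.1.1 and the protocol GE1_1105_Oct12, whereas the submitters' processing notes name version 10.10.1.1. The deposited series table gives an intensity for each spot that equals the processed signal times 1 constant per array (2.14, 2.10, 1.95 and 2.02 for normal, regenerated, overloaded and regenerated overloaded). The values are on a linear scale and are not centred, and what the authors chose the constant from is unknown.

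Each array has 62976 spots, 58717 of them probe spots. Spots with an outlier flag, between 406 and 451 probe spots per array, were left out, and no spot was saturated. The 30367 probes were printed once (13137), 2 times (15840) or 10 times (1390). The median processed signal was 84.0, 99.6, 112 and 111 intensity units for normal, regenerated, overloaded and regenerated overloaded muscle, and the median signal of the negative control spots 59, 48, 44 and 46. The lowest processed signal called well above background was 27.7, 16.3, 15.6 and 18.6. The number of arrays limits the precision. Over probes well above background with more than 1 spot, the SD between spots was 0.11, 0.10, 0.13 and 0.11 on the log2 scale, and 0.48, 0.46, 0.56 and 0.53 over the other probes.

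The files' headers place the probes on build rn4, and the reference table of gene names is of assembly GRCr8, so it was used for names alone and no coordinates are given. By accession, 18643 probes matched 15637 gene symbols, and 11724 probes under 10996 names did not, so that 26633 genes and transcripts were analysed. Unmatched names enter the totals and are not named in the text.

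The log2 processed signal of each spot was reduced by the log2 of the array's 75th percentile, spots of a probe were averaged, and a gene was read from its probe with the highest mean over the 4 arrays. A gene was measured in a comparison where that probe was well above background on at least 1 of the 2 arrays. Where it was above background on 1 array alone, its fold was taken against the lowest signal called well above background on the other array if that was higher, and is given as an at-least fold. Genes were counted as higher or lower at 2-fold or more. With 1 array per group no test between groups was run and no p-value is given, and a fit with regeneration and overload as separate effects, which would leave 1 residual degree of freedom, was not made. Technical standard errors were computed from the SD between spots of a probe, pooled over probes of like signal on the array, and from each probe's number of spots.

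The comparisons were regenerated against normal, overloaded against normal, regenerated overloaded against regenerated and regenerated overloaded against overloaded muscle. The difference of differences (the overload difference in regenerated minus that in normal muscle) used genes well above background on all 4 arrays. Genes shared by 2 comparisons were counted where these had no array in common, beside the number expected for independent calls. The groups, comparisons, lists, naming rule and the alternatives not marked otherwise were fixed before the data were examined.

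For each of 29 gene lists the median log2 difference of its measured members was placed among 10000 random lists of the same size matched in 20 bins of mean signal (seed 1), as a description of these arrays. Medians among the 2.5% at either end are called outside the random lists. The lists were slow contractile, fast contractile, developmental sarcomere, satellite cell and myogenic regulators, neuromuscular junction and denervation, load-responsive muscle, IGF and myostatin signalling, atrophy and autophagy, heat shock, ribosome biogenesis, oxidative phosphorylation and TCA cycle, fatty acid oxidation, glycolysis and glycogen, collagens, matrix and matrix remodelling, macrophage and myeloid, lymphocyte, neutrophil and blood, adipocyte, endothelial, smooth muscle and pericyte, fibro-adipogenic progenitor and fibroblast, Schwann cell, tendon and cartilage, cell cycle, interferon response, MHC class II antigen presentation, circadian, and immediate early genes. This gave 116 medians over the 4 comparisons.

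The genes named were the 10 with the largest difference in each direction among those above background on both arrays, the 5 with the largest at-least fold in each direction, up to 4 members of each list with the largest absolute difference, and the 10 largest differences of differences in each direction. Genes without a symbol of their own were left out of these. A part of the genes that this rule selects is not reported here. Pvalb, Ppargc1a and Cdkn2b, and Cdk1, Tnnt3 and Myh4 in overloaded against normal muscle, fall outside this rule and were chosen after their values were seen.

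The alternatives were quantile normalization, cyclic loess, the median of each array or the authors' factor in place of the 75th percentile, normexp background correction (offset 50) with quantile normalization, no filter on dim probes or a stricter one, a floor on low signals, the mean over a gene's probes, leaving out saturated probes, and a 1.5-fold limit for shared genes. The planned normexp correction used the median in place of the mean spot signal, which is not among the columns. After the data were seen, 3 alternatives were added: without spots in the outer 16 rows at either end (for named genes too), without probes printed once, and the smallest difference between any spots of the 2 arrays.

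The calling step was tested on simulated data with the spot noise of these arrays and 50 genes at each of several folds. The noise was drawn from a normal distribution with the technical standard errors, and stray spots such as those in the outer rows were not simulated. The number called among unchanged genes is therefore not the number of false calls on the real arrays. Unchanged genes include those at background. At 3-fold, 50, 49, 47 and 47 of 50 were called in simulations of regenerated against normal, overloaded against normal, regenerated overloaded against regenerated and regenerated overloaded against overloaded muscle, and at 2-fold 22, 24, 24 and 17. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normexp, quantile normalization and cyclic loess.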

Results

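Gene expression was measured in the soleus, a slow postural muscle of the lower leg, of male rats on 4 one-colour Agilent arrays. The 4 groups were normal muscle, regenerated muscle, overloaded muscle and regenerated overloaded muscle, and RNA of 6 muscles per group was mixed in equal amounts for 1 array. Every group therefore had n = 1, and no difference between groups has a replicate check. Normal and regenerated muscle came from rats aged 16 weeks, and both overloaded groups came from rats aged 18 weeks. Regenerated muscle was taken 8 weeks after an injection named CTX in the labels, which do not expand it (in regeneration work the letters usually stand for cardiotoxin, a snake venom toxin that destroys muscle fibres). The overloaded muscle is labelled as hypertrophied, and the labels do not say how the load was raised. The sample titles end in R for normal and overloaded muscle and in L for both regenerated groups, letters that the labels do not expand, and whether groups of the same age came from the same rats is not stated.

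The share of spots well above background was 60.2% on the normal array, 68.8% on the regenerated array, 70.4% on the overloaded array and 67.9% on the regenerated overloaded array. The normal array also had the highest median local background, 44 intensity units against 33, 32 and 32. The number of arrays limits the precision, and the errors given below are technical: they come from repeated spots of a probe on the same array. A gene counts as higher or lower where the 2 arrays differ 2-fold or more. Of 30367 probes, 18643 matched 15637 gene symbols, and the rest enter in totals alone.

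The comparison of regenerated with normal muscle concerns what remained 8 weeks after the injection. Regenerated muscle had 5.53-fold more signal of Ccn5, a matricellular protein (log2 difference 2.47, technical SE 0.078), and 4.39-fold more of Apoe, the lipid-carrying apolipoprotein E. Postn, the matrix protein periostin, was 4.03-fold higher and Ccl11, the eosinophil-attracting chemokine eotaxin, 3.77-fold higher. Mcpt9 and Mcpt8, proteases of a family found in mast cells and basophils, were 5.33-fold and 4.83-fold higher, and Mcpt10 was at least 4.68-fold higher. Among genes well above background in regenerated muscle alone, Anxa8, an annexin, was at least 8.90-fold higher and Cdkn2a, which encodes inhibitors of the cell cycle, at least 6.76-fold higher (3.87-fold and 3.18-fold with normexp background correction, which draws dim signals together). Myh2, the heavy chain of the fast myosin 2A, was 3.26-fold lower (log2 difference -1.71, technical SE 0.055), and Myom2, a protein of the sarcomere's M-band, was 3.22-fold lower.

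Other genes with large positive differences were Atp1b4 (3.87-fold), Sncg (3.85-fold), Gdf10 (3.77-fold), a member of the TGF-beta family, and Aebp1 (3.69-fold). Il1rn, the antagonist of the interleukin-1 receptor, was at least 3.81-fold higher. Dnmt3l (4.56-fold), Amy1 (3.71-fold), an amylase, Kera (2.99-fold), the small proteoglycan keratocan, and Pik3c2g (2.80-fold) were lower. Ifgga2l2 (5.82-fold), Lnx1 (5.62-fold) and Qrich1 (3.78-fold) were also lower, and each had a spot in the outer 16 rows of the array. In all, 324 of 16911 measured genes and transcripts differed 2-fold or more, 212 higher and 112 lower; the normal array had the lowest share of spots above background, 60.2% against 68.8%.

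Of the 12 measured collagens, 4 were 2-fold or more higher, none was lower and 8 passed neither limit, with Col3a1 at 1.63, Col1a1 at 1.37, Col5a1 at 1.33 and Col6a2 at 1.05 on the log2 scale. Their median was 0.93, percentile 100 among 10000 random lists of like expression. Of 21 measured matrix genes, 8 were higher and 13 passed neither limit, including Eln (elastin, 1.66), Mmp14 (1.27) and Fn1 (fibronectin, 1.22), with a median of 0.87 (percentile 100). The adipocyte list had a median of 0.91 (percentile 100), with 4 of 11 members higher: Scd at 1.72, Retn (resistin) at 1.51, Cfd (adipsin) at 1.13 and Fasn at 1.02. The macrophage and myeloid list had a median of 0.61 (percentile 100), with 2 of 22 members higher, Gpnmb at 1.22 and Cd68 at 1.05. In the list of IGF and myostatin signalling, 4 of 18 members were higher: Fst (follistatin, 1.12), Igfbp5 (1.04), Igfbp4 (1.04, from 1 spot) and Igf1 (1.02), with a list median of 0.11 (percentile 99.6; between 0.02 and 0.24 over the scalings). The fibro-adipogenic progenitor and fibroblast list had a median of 0.48 (percentile 100) and 1 of 9 members higher, Osr1 at least 2.30-fold.

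The fast contractile list had 2 of 14 members lower, Myh2 and Tpm1 (-1.06), 1 higher, Myh4 (1.15), the myosin 2B heavy chain, and a median of -0.33 (percentile 0). Over the scalings that median lay between -0.42 and -0.09, and between -0.22 and -0.04 relative to all genes. Of 11 slow contractile genes, 1 was lower: Pln, the SERCA inhibitor phospholamban, at -1.14. The slow list's median was -0.24 (percentile 4.47) and turned to 0.03 under cyclic loess scaling. Medians near 0 have to be read against the median of all 14449 genes above background on both arrays, which was -0.11, and which other scalings put between -0.20 and 0.02. The interferon list (0.36, percentile 99.99), the MHC class II list (0.39, percentile 99.9) and the lymphocyte list (0.58, percentile 98.9, and 0.17 with normexp) had positive medians without a member past 2-fold. The cell cycle list's median was 0.36 (percentile 99.7), 0.11 with normexp, 0.19 with the mean over a gene's probes, and 0 with genes above background on 1 array set at their smallest fold.

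With normally distributed spot noise alone, a simulation of this comparison called 103 of 26433 unchanged genes, those at background included. Stray spots were not simulated. Of 51 named genes past 2-fold, 18 had a fold over 1.5 times smaller with normexp, among them Ccn5 (3.18), Mcpt10 (2.14) and Il1rn (2.01). Without spots in the outer rows, Lnx1 (-0.94 on the log2 scale) and Osr1 (0.78) ended under 2-fold. The count of 324 was 116 under normexp background correction with quantile normalization, 188 without probes printed once, 199 with genes above background on both arrays, 88 at the smallest difference between spots, and 2209 without the filter on dim probes; Amy1, Dnmt3l, Myh4, Tpm1, Pln, Igfbp5, Cd68, Fasn and Osr1 ended under 2-fold with normexp, Tpm1 (-0.91) and Fasn (0.99) with quantile normalization, and Tpm1 with the authors' factor (-0.93) and with the mean over its probes (-0.37).

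The comparison of overloaded with normal muscle concerns overload of muscle that was not injured. Cthrc1, a secreted protein with collagen-like repeats, was 8.79-fold higher in overloaded muscle (log2 difference 3.14, technical SE 0.17) and Postn 8.61-fold higher (3.11, technical SE 0.096). Sfrp4 and Sfrp2, secreted modulators of Wnt signalling, were 6.21-fold and 4.61-fold higher. Mmp14, a membrane-bound metalloproteinase, was 4.82-fold higher, Fbn2 (fibrillin 2) 4.82-fold and Col3a1, the chain of type III collagen, 4.41-fold. Myh2 was 6.85-fold lower (log2 difference -2.78, technical SE 0.056), Tnni2, the fast isoform of troponin I, 4.96-fold lower, and Myh1, the myosin 2X heavy chain, 3.30-fold lower.

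Igsf10 (5.62-fold), Cpz (5.55-fold), a carboxypeptidase, and Klk1c3 (4.12-fold, 1 spot) completed the 10 largest positive differences. Among genes above background in overloaded muscle alone, Tox was at least 8.41-fold, Steap1 at least 5.07-fold and Armh4 at least 4.29-fold higher on 1 spot each, that of Tox in the outer rows, Lrrc17 was at least 3.92-fold and Trh, the precursor of thyrotropin-releasing hormone, at least 3.60-fold higher. Mup5 (4.30-fold), Mup4 (3.49-fold, both spots in the outer rows) and Obp3 (3.49-fold, 1 spot) were lower; the 3 belong to a family of near-identical genes, and their probes cannot be taken as specific to 1 of them. Dnmt3l was at least 5.95-fold lower and Ppp1r42 at least 5.33-fold on 1 spot, which gave no fold with normexp. In all, 546 of 17308 genes and transcripts differed 2-fold or more, 418 higher and 128 lower, the largest count of the 4 comparisons and the one between the arrays with the lowest and highest shares of spots above background, 60.2% and 70.4%.

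Of 12 collagens, 8 were higher and 4 passed neither limit, with a median of 1.21 (percentile 100) and Col1a1 at 1.83, Col5a1 at 1.51 and Col14a1 at 1.44. Of 22 matrix genes, 14 were higher and 8 passed neither limit, with a median of 1.15 (percentile 100) and Loxl1, a lysyl oxidase that cross-links elastin, at 1.59. The cell cycle list had 3 of 17 members higher, Rrm2 at 1.77, Ccna2 (cyclin A2) at least 3.13-fold and Cdk1 (1.44), with a median of 0.98 (percentile 100), or 0.31 with normexp and 0.36 with genes above background on 1 array set at their smallest fold. The interferon list had 4 of 16 members higher, Isg15 at 1.51, Rsad2 at 1.19, Mx1 at 1.15 and Cxcl10 at least 3.42-fold, with a median of 0.81 (percentile 100). The macrophage and myeloid list had 3 of 22 members higher, Adgre1 at 1.21, Ccl2 at 1.21 and Cd68 at 1.02, with a median of 0.83 (percentile 100). The MHC class II list had 2 of 9 members higher, RT1-Da at 1.22 and Cd74 at 1.03, with a median of 0.75 (percentile 100), or 0.46 with genes above background on 1 array at their smallest fold. The lymphocyte list (0.80, percentile 99.3, and 0.19 with normexp) had no member past 2-fold, and the fibro-adipogenic progenitor and fibroblast list had a median of 0.62 (percentile 100) with 2 of 9 members higher, Mfap5 at 1.05 and Thy1 at least 2.19-fold.

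The fast contractile list went both ways, with 4 of 14 members lower, Myh2, Tnni2, Myh1 and Tnnt3, and 2 higher, Actn3 (1.99), the fast-fibre alpha-actinin, and Myh4 (1.39). Its median was -0.67 (percentile 0; between -0.79 and -0.42 over the scalings). Myh3, the embryonic myosin heavy chain, was 1.62 higher and Tnnt2, the cardiac troponin T found in developing muscle, 1.21 higher on the log2 scale, 2 of 6 members of the developmental sarcomere list (median 0.10, percentile 99.8; between -0.01 and 0.28 over the scalings). The slow contractile list had a median of -0.31 (percentile 13.04), between -0.42 and 0.07 over the scalings, and Pln at -1.11. Of the immediate early genes, Fos (1.75) and Egr1 (1.05) were higher, 2 of 12 (median 0.43, percentile 99.97). The lists of oxidative phosphorylation (-0.41, percentile 0.01), fatty acid oxidation (-0.34, percentile 1.25) and glycolysis (-0.43, percentile 0) had medians under that of all genes, -0.12, with 1 member past 2-fold, Fbp2 (-1.06). Over the scalings these medians lay between -0.52 and -0.15, -0.45 and -0.14, and -0.55 and -0.24, and relative to all genes the first lay between -0.28 and -0.09. In the circadian list Npas2 and Bmal1 (1.07 each) were higher and Ciart (-1.31, 1 spot) lower, 3 of 14 members, with a median of -0.40 (percentile 0.01; between -0.52 and -0.23 over the scalings).

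The overloaded rats differed also in age (18 against 16 weeks) and in the row on the slide, so these cannot be told apart from load, and spot noise alone called 127 of 26433 unchanged genes in a simulation of this comparison; of 61 named genes past 2-fold, 22 had a fold over 1.5 times smaller with normexp, among them Cthrc1 (4.85), Cpz (3.315), Fbn2 (2.775) and Sfrp2 (2.73), and Egr1 (0.92 on the log2 scale) ended under 2-fold without spots in the outer rows. The count of 546 was 212 with normexp and quantile normalization, 334 without probes printed once, 169 at the smallest difference between spots and 5698 without the filter on dim probes; Mup4, Armh4, Pln, Fbp2, Adgre1, Ccl2, Cd68, Thy1, Ccna2, Rsad2, Mx1, Ciart, Npas2, Bmal1, Egr1 and Lrrc17 ended under 2-fold with normexp, Tox, Rrm2, Npas2 and Bmal1 with the mean over a gene's probes, Fbp2, Thy1 and Npas2 with quantile normalization, and Pln and Fbp2 with the authors' factor.

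The comparison of regenerated overloaded with regenerated muscle concerns overload after injury. The labels give the time since the injection for regenerated muscle alone, so that time may also differ between these groups. Tnn, tenascin N, was at least 57.7-fold higher after overload, Scg2, the granule protein secretogranin II, at least 13.8-fold, and Tnc, tenascin C, at least 6.54-fold; each was above background after overload alone. With normexp these folds were 12.55, 4.25 and 2.23, and that of Tnn was 14.1 with the mean over its probes. Cthrc1 was 6.68-fold higher (log2 difference 2.74, technical SE 0.069), Mt3, a metallothionein, 5.01-fold and Postn 4.12-fold. Lrrc15 (4.85-fold), Fcrl2 (4.71-fold), Rab15 (4.56-fold), C1qtnf3 (4.01-fold) and Vegfb (3.81-fold), a growth factor of the VEGF family, were also higher, as was Slc25a15, the mitochondrial ornithine carrier, at least 6.04-fold, and Jpt2l1, on 1 spot, at least 6.32-fold. Aqp4, the water channel of the fibre membrane, was 2.73-fold lower (log2 difference -1.45, technical SE 0.078) and Fkbp5, a glucocorticoid-induced chaperone, 2.43-fold.

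Igll1 (3.60-fold) and Pou2af1 (2.79-fold), both genes of B cells, Cish (2.69-fold, 1 spot), a suppressor of cytokine signalling, and Arrdc2 (2.32-fold) were lower. Trim16 was 2.26-fold lower on its brightest probe, and its probes disagreed in sign. Clec2d2l1 (6.69-fold) and Zfp319 (4.39-fold) were higher on 1 spot each. The 5 largest at-least folds on the lower side, were those of Cfap206 (1 spot), Cldn24 (2.93), Gnmt (2.52), Adrb3 (2.28) and Glp1r (2.21). In all, 342 of 17208 genes and transcripts differed 2-fold or more, 266 higher and 76 lower.

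The tendon and cartilage list had 4 of 8 members higher, Tnmd (tenomodulin, 1.61), Kera (1.46), Comp (cartilage oligomeric matrix protein, 1.21) and Fmod (fibromodulin, 1.18), and a median of 1.004 (percentile 100). Of 22 matrix genes, 8 were higher and 14 passed neither limit, with a median of 0.78 (percentile 100) and Lum (lumican) at 1.56. Of 12 collagens, 2 were higher, Col11a1 at 1.81 and Col1a1 at 1.07, and 10 passed neither limit, with a median of 0.52 (percentile 100). The cell cycle list had 4 of 17 members higher, Ccna2 (1.56), Rrm2 (1.35), Birc5 (1.13) and Cdk1 (1.12), and a median of 0.70 (percentile 100), or 0.22 with normexp. The macrophage and myeloid list had a median of 0.27 (percentile 100) and 1 of 22 members higher, Ccl2, a chemokine of monocytes, at 1.28. The fibro-adipogenic progenitor and fibroblast list had 1 of 9 members higher, Thy1 (1.73), and a median of 0.27 (percentile 99.96). Myh3 (1.32) and Tnnt2 (1.42) were higher, as were Mustn1 (1.63) and Ankrd1 (1.47), a stretch-induced ankyrin repeat protein, 2 of 12 members of the load-responsive list (median -0.16, percentile 2.35; between -0.22 and -0.07 over the scalings). The median of the developmental sarcomere list was 0.10 (percentile 98.4; between 0.04 and 0.16 over the scalings).

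The fast contractile list had Tpm1 (1.12) and Myl11 (1.05) higher and Myh4 (-1.12) lower, 3 of 14 members, and a median of -0.06 (percentile 32.9), which turned to 0.04 under 1 of the scalings. The slow contractile median was -0.18 (percentile 0.945; between -0.24 and -0.05 over the scalings). No member of the lists of oxidative phosphorylation (-0.29), fatty acid oxidation (-0.38) and glycolysis (-0.29) passed 2-fold, and each median lay at percentile 0, the first between -0.36 and -0.19 over the scalings. The adipocyte list had a median of -0.22 (percentile 0.84) with all 11 members on the negative side. Fos (1.63) and Egr1 (1.30) were higher, and the immediate early list's median was 0.08 (percentile 93.6). Bmal1 (1.40) was higher and Ciart (-1.18, 1 spot) lower, with a circadian median of -0.32 (percentile 0). The interferon list (0.06, percentile 88.9), the MHC class II list (0.16, percentile 98.6) and the lymphocyte list (0.21, percentile 92.3) had no member past 2-fold. Over the scalings the MHC class II median lay between 0.10 and 0.23 and the lymphocyte median between 0.07 and 0.26.

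Age and slide row differed here as in the other overload comparison, and a simulation with spot noise alone called 136 of 26433 unchanged genes; of 54 named genes past 2-fold, 20 had a fold over 1.5 times smaller with normexp, among them Jpt2l1 (2.41), Slc25a15 (2.27) and Lrrc15 (2.07), Rrm2 was 4.42-fold higher with the mean over its probes, and Adrb3 (-0.80 on the log2 scale) ended under 2-fold without spots in the outer rows. The count of 342 was 102 with normexp and quantile normalization, 182 without probes printed once, 227 with genes above background on both arrays, 92 at the smallest difference between spots and 1460 without the filter on dim probes; with normexp Igll1, Pou2af1, Cish, Arrdc2, Ciart, Myh4, Thy1, Kera, Ccna2, Rrm2, Birc5, Cdk1, Cfap206, Cldn24, Gnmt, Adrb3 and Glp1r ended under 2-fold, and with the mean over a gene's probes Pou2af1, Cish, Trim16, Tpm1 and Col1a1 did, while Cfap206 and Glp1r gave no fold.

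**Figure D1:**
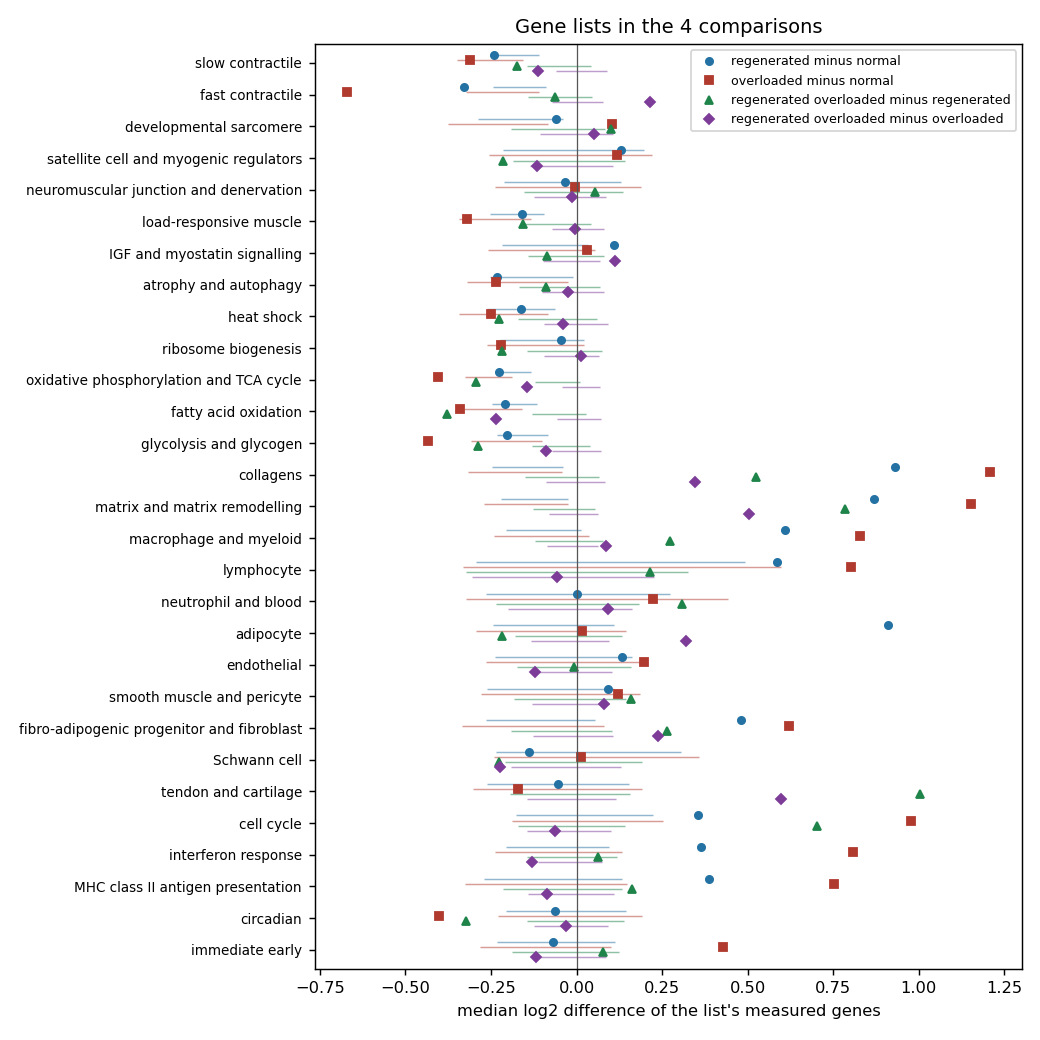
Median log2 difference of each of the 29 gene lists (horizontal axis) in the 4 comparisons of 2 arrays (symbols), with a line over the medians of 10000 random lists of like expression, leaving out 2.5% at each end. Collagens lay between 0.35 and 1.21 and matrix genes between 0.50 and 1.15, right of the random lists in all 4 comparisons.

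The comparison of regenerated overloaded with overloaded muscle concerns the earlier injury in muscles that were both overloaded at the same age. Tnn was 33.9-fold higher in regenerated overloaded muscle and Anxa8 6.22-fold higher (log2 difference 2.64, technical SE 0.13), or 9.97-fold and 2.44-fold with normexp. Myh1 was 4.92-fold higher (log2 difference 2.30, technical SE 0.062), Cdkn2a 4.89-fold (2.52 with normexp) and Lrrc15 3.96-fold. Myh4 was 2.57-fold lower (log2 difference -1.36, technical SE 0.080), Pik3c2g 2.75-fold lower and Amy1, above background in overloaded muscle alone, at least 6.67-fold lower. Slc25a15 was at least 6.76-fold and Rp1 at least 6.28-fold higher.

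The other genes among the largest differences lower in regenerated overloaded muscle, Tox (10.6-fold), Cd209f (7.76-fold), Rad54l, Sytl4, Acot4, Akr1c3, Ccdc175 and Adat2, each rested on 1 spot, as did Zfp319 (4.66-fold), Clec2d2l1 (4.57-fold) and Ctxn3 (3.70-fold) among the higher ones. In all, 295 of 17493 genes and transcripts differed 2-fold or more, 176 higher and 119 lower, and 59.0% of the 295 were read by probes printed once, against 40.8% of the measured genes.

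The fast contractile list had 3 of 14 members higher, Myh1, Myh2 (1.33) and Pvalb (parvalbumin, 1.05), and 2 lower, Myh4 and Actn3 (-1.33), with a median of 0.22 (percentile 100). The tendon and cartilage list had 3 of 8 members higher, Comp (1.70), Chad (chondroadherin, 1.64) and Fmod (1.32), with a median of 0.60 (percentile 100). Of 12 collagens, 1 was higher, Col11a1 (1.36), with a median of 0.35 (percentile 100), and of 22 matrix genes 2 were higher, Tnc (1.56) and Ltbp2 (1.35), with a median of 0.50 (percentile 100). Ankrd1 was 1.16 higher, 1 of 12 members of the load-responsive list (median 0.00, percentile 28.9, with its sign changing over the scalings). The adipocyte list (0.32, percentile 100), the fibro-adipogenic progenitor and fibroblast list (0.24, percentile 99.97) and the macrophage and myeloid list (0.09, percentile 99.5; between 0.05 and 0.12 over the scalings) had positive medians without a member past 2-fold. The interferon list had a median of -0.13 (percentile 0.93) with Cxcl10 at -0.996, just under the limit. The lists of oxidative phosphorylation (-0.14, percentile 0), fatty acid oxidation (-0.23, percentile 0), glycolysis (-0.09, percentile 0.96) and slow contractile genes (-0.11, percentile 0.315) had negative medians without a member past 2-fold. The MHC class II (-0.09), lymphocyte (-0.06) and cell cycle (-0.06) lists had no member past 2-fold either, with medians inside the random lists.

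A simulation of this comparison with spot noise alone called 217 of 26433 unchanged genes, and 44 of 15245 on probes printed more than once, where 121 were counted; of 39 named genes past 2-fold, 26 had a fold over 1.5 times smaller with normexp, among them Amy1 (2.39), Rp1 (2.10) and Slc25a15 (2.09), and with the mean over a gene's probes Tnn was 22.6-fold and Rp1 at least 3.32-fold higher and Tox 3.215-fold lower. The count of 295 was 56 with normexp and quantile normalization, 121 without probes printed once, 144 with genes above background on both arrays, 48 at the smallest difference between spots and 1438 without the filter on dim probes; Lrrc15, Zfp319, Rad54l, Sytl4, Acot4, Ccdc175, Adat2 and Tnc ended under 2-fold with normexp, and Sytl4 with the mean over its probes (-0.32).

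The overload difference could be compared between normal and regenerated muscle without sharing an array. Of 16725 genes measured in both, 96 were 2-fold or more higher after overload in both kinds of muscle, where 5.16 would be expected if the calls were independent, and 17 were lower in both (expected 0.28). Age and slide row differed in the same way in both comparisons, and whether pools of the same age came from the same rats is not stated, so the calls need not be independent. The 96 include Cthrc1, Postn and Mmp14 of the matrix list, Col1a1 of the collagens, and Fbn2, Sfrp4 and Igsf10. They also include the cell cycle genes Ccna2 and Rrm2, the transcription factor genes Fos and Egr1, the chemokine gene Ccl2, and Myh3, Tnnt2, Mt3 and Bmal1. The 17 include Cish, Ciart and Trim16, and Ppargc1a, a coactivator of mitochondrial gene expression chosen after its values were seen, at -1.28 in normal and -1.12 in regenerated muscle (-0.82 and -0.54 with normexp, which end both calls). The log2 differences correlated across 14417 genes above background on all 4 arrays (Pearson 0.65, Spearman 0.65; genes are not independent replicates). With normexp and quantile normalization, 42 genes were shared, 40 higher and 2 lower. Ciart (-0.81 and -0.66) and Ccna2 (0.85 and 0.57) also lost both calls there. Cish, Trim16, Col1a1, Rrm2, Egr1, Ccl2 and Bmal1 lost a call or more with normexp or the mean over a gene's probes.

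**Figure D2:**
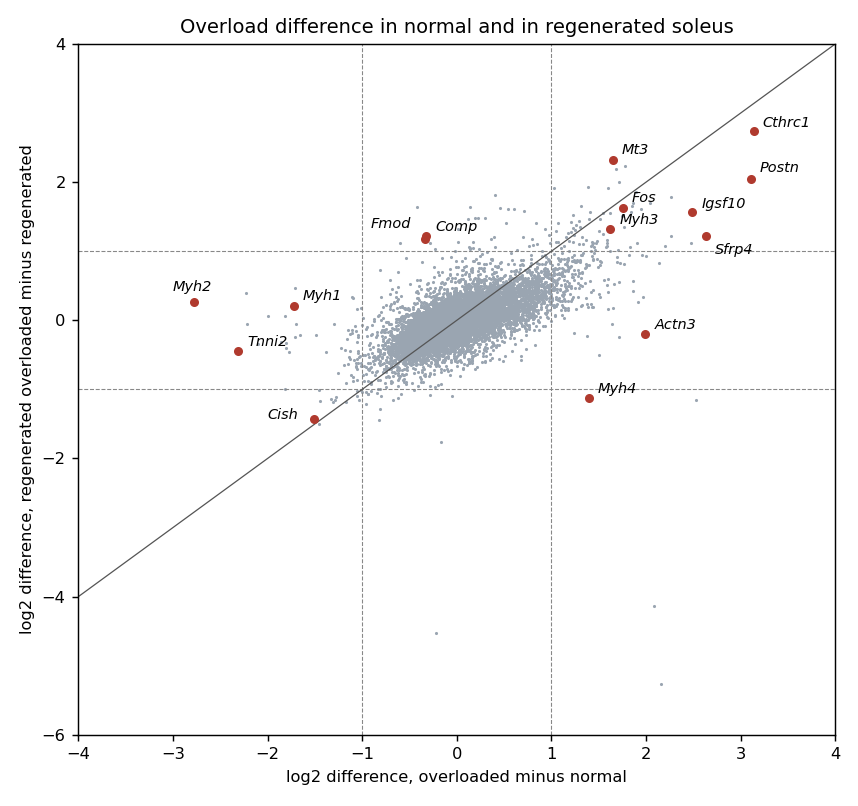
Log2 difference after overload in normal muscle (horizontal axis) and in regenerated muscle (vertical axis), 1 point for each of 14417 genes above background on all 4 arrays, with the 2-fold limits dashed and a diagonal of equal differences. Cthrc1 and Postn lie far from 0 on both axes, while Myh2 and Tnni2 lie at -2.78 and -2.31 in normal muscle and at 0.26 and -0.44 in regenerated muscle.

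The regenerated muscle's difference from uninjured muscle was compared in the same way without and with overload. Of 16613 genes measured in both, 31 were higher in both (expected 1.31) and 13 lower in both (expected 0.28). Those higher in both include Anxa8, Cdkn2a, Ccn5, Atp1b4, Sncg, Ccl11, Mcpt8, Ltbp2, Ctxn3 and Rp1, and those lower in both include Amy1, Pik3c2g and Cd209f (1 spot). The correlation across the 14417 genes was lower (Pearson 0.51, Spearman 0.48). With normexp and quantile normalization 12 genes were shared, and 24 with genes above background on all 4 arrays.

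The overload response itself differed 2-fold or more between regenerated and normal muscle for 110 of 14417 genes, 54 with a higher and 56 with a lower value in regenerated muscle. No simulation of spot noise was made for this count, and 39 of the 110 were read by probes printed once. Myh2 was 6.85-fold lower after overload in normal muscle and 1.20-fold higher in regenerated muscle, a difference of differences of 3.04 on the log2 scale (technical SE 0.079). Myh1 (1.93), Tnni2 (1.87) and Tpm1 (1.71) also had higher values in regenerated muscle, while Myh4 (-2.52), Actn3 (-2.19), Pcsk1n (-2.001), Scd (-1.69), Cdkn1c, a cell cycle inhibitor (-1.62), Mcpt9 (-1.47), Apoe (-1.43) and Anpep (-1.42) had lower ones. Mup5 was at 1.76. Ifgga2l2 (2.63), Lnx1 (2.16), Zfp316 (2.05), Qrich1 (1.88), Snx11 (1.64) and Adat2 (-1.44) also differed, and Acot4 (-1.96) rested on 1 spot. A spot in the outer rows was the only one of Ifgga2l2, Zfp316, Qrich1, Snx11 and Adat2 and 1 of 2 spots of Lnx1, Myh4, Actn3 and Scd, which were at 0.72, -2.49, -2.18 and -1.68 without it. For Ifgga2l2, Lnx1, Zfp316, Qrich1 and Snx11 the normal array alone stood apart, so their values rest on that array. Ifgga2l2 was at -0.99 there, against -3.53 in regenerated, -3.22 in overloaded and -3.13 in regenerated overloaded muscle.

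Across lists, 6 of 14 fast contractile genes had a higher value in regenerated muscle and 2 a lower one, with a median of 0.71. Of 7 tendon and cartilage genes 5 had a higher value, with a median of 1.34. The most negative medians, against 0.07 over all genes, were those of the collagens (-0.64, SD between members 0.67, with 1 of 12 members 2-fold or more higher and 2 lower), the interferon list (-0.59, 1 of 15 lower), the adipocyte list (-0.45, 1 of 10 lower) and the matrix list (-0.42, 3 of 21 lower), and of the macrophage and myeloid list (-0.52), the lymphocyte list (-0.48, 4 genes) and the MHC class II list (-0.42), which had no member past 2-fold. Over the scalings the lymphocyte median lay between -0.61 and -0.30. No interaction test is possible with 1 array per group. The count was 39 with normexp and quantile normalization, 71 without probes printed once and 5587 without the filter on dim probes; Mup5, Zfp316, Snx11, Acot4 and Adat2 ended under 2-fold with normexp, where Myh4 was at -1.87, Ifgga2l2 at 1.71, Lnx1 at 1.39, Qrich1 at 1.27 and Pcsk1n at -1.18, and Tpm1 and Zfp316 with the mean over a gene's probes.

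**Figure D3:**
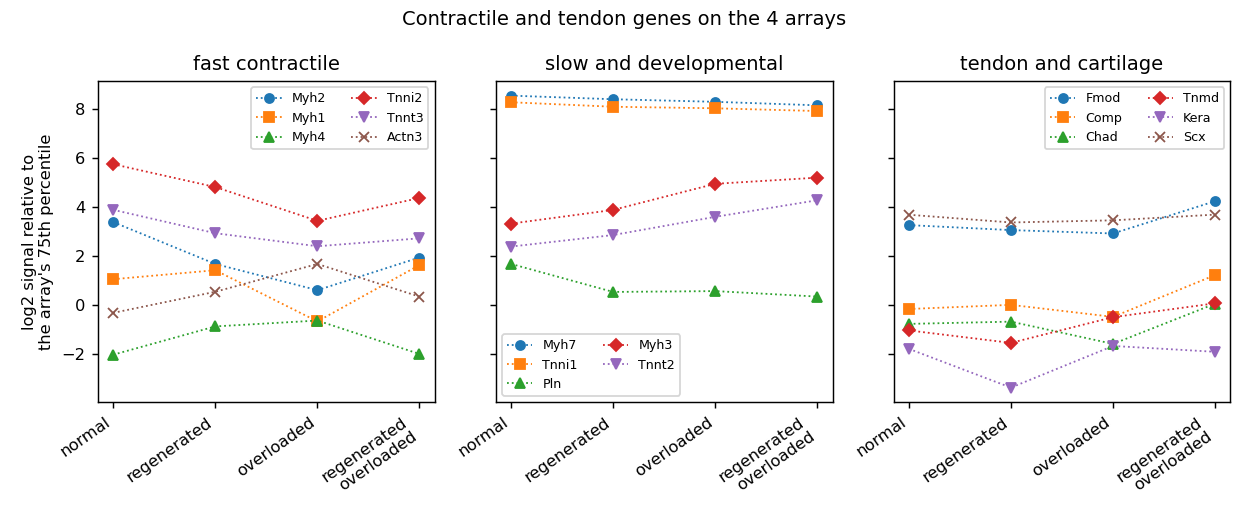
Log2 signal of contractile and tendon genes relative to the array's 75th percentile (vertical axis) on the 4 arrays, 1 array per group, with dotted lines to guide the eye. Myh2 was at 3.39 in normal and 0.62 in overloaded muscle, and at 1.69 in regenerated and 1.95 in regenerated overloaded muscle, while Fmod had 4.25 in regenerated overloaded muscle and between 2.93 and 3.27 on the other arrays.

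Genes 2-fold or more higher on 1 array than on each of the other 3 numbered 177: 60 on the normal, 23 on the regenerated, 38 on the overloaded and 56 on the regenerated overloaded array. Of these, 137 were read by probes printed once (77.4%, against 41.2% of the 17791 genes above background on any array). On the normal array, 32 of the 50 such genes lay in the last 16 rows, among them Slc5a1l1 (at least 21.8-fold higher than in regenerated and 24.4-fold than in overloaded muscle), Zmynd12 (11.8-fold and 13.2-fold) and Accsl (10.6-fold and 11.9-fold). Of probes with 2 spots on that array, 6.29% of those with a spot in the outer rows and 1.33% of the others had spots 2-fold apart.

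**Figure D4:**
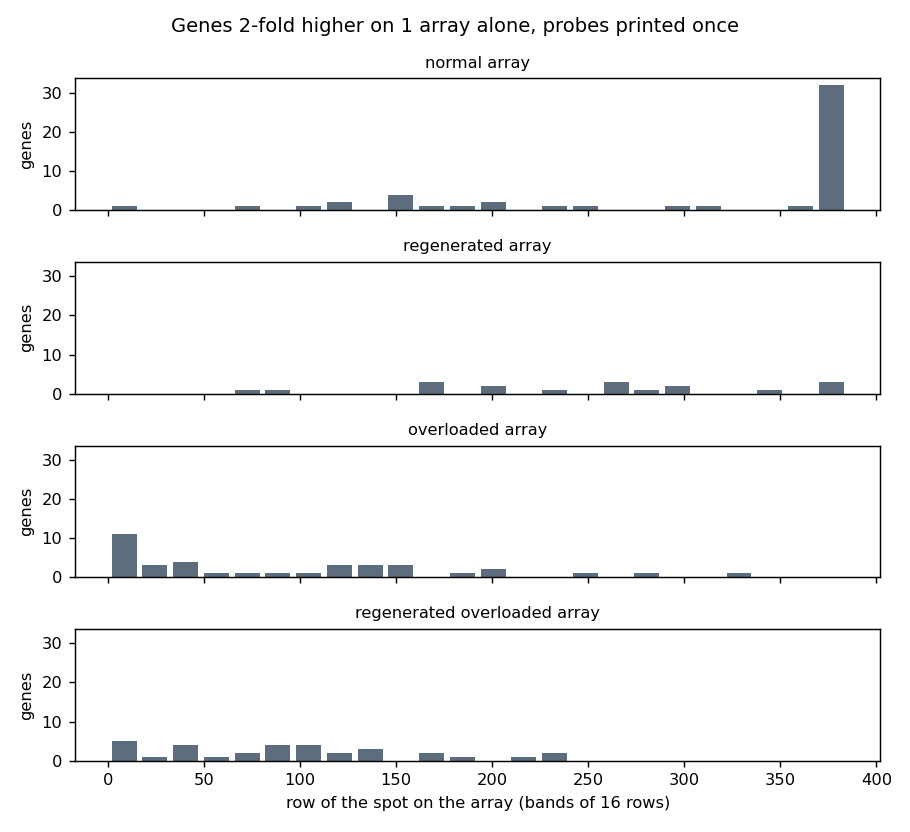
Number of genes 2-fold or more higher on 1 array alone and read by probes printed once (vertical axis), by row of the spot on the array in bands of 16 rows (horizontal axis), 1 panel per array. The last band of the normal array holds 32 genes and the first band of the overloaded array 11.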

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

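The tests in this part were chosen after the results were seen, except the one on probes of matched brightness.

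Pairs of comparisons without a shared array were searched for genes past 2-fold in opposite directions. Myh4 had a log2 difference of 1.393 between overloaded and normal muscle and of -1.124 between regenerated overloaded and regenerated muscle. It also had 1.154 between regenerated and normal muscle and -1.363 between regenerated overloaded and overloaded muscle, where Myh2 had -1.707 and 1.332. Both pairs of Myh4 come from the same 4 arrays, so they are not separate results. With normexp these 4 differences of Myh4 were 1.01, -0.85, 0.84 and -1.03, so that 1 call of each pair was lost. Fam167a, read from 1 spot, had -1.33 after overload in normal and 1.27 in regenerated muscle. The latter was taken against the regenerated array's own signal, which was not well above background. With normexp (-0.59 and 0.43) and the mean over its probes (-0.63 and 0.65) both ended under 2-fold. With 1 array per group none of these differences was tested.

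Fast contractile genes went in opposite directions after overload, and differently in normal and regenerated muscle. Between-array scaling is argued against, since 6 of the 8 genes with a difference of differences of 2-fold or more stayed past it by more than 2 technical standard errors under each of quantile normalization, cyclic loess and normexp, Myh4 and Actn3 lower and Myh1, Myh2, Tnni2 and Tpm1 higher, while Pvalb ended under it (0.97, 0.94 and 0.94). Cross-hybridisation between myosin heavy chain genes would not reach the 5 other genes with a difference of differences of 2-fold or more (Tnni2, Tnnt3, Tpm1 and Pvalb in one direction, Actn3 in the other). These genes therefore cannot test it for the myosins, where it stays open. RNA of a fast muscle in the normal pool was not tested and stays open for Myh2, Tnni2 and Tnnt3, which were highest on the normal array. It would not explain Myh4 and Actn3, which had their lowest values on the normal array. They were at -2.01 and -0.31 there, against -0.62 and 1.69 in overloaded muscle. Nor would it by itself account for Myh1, at 1.07 on the normal array. Myh1 was higher in regenerated (1.43) and regenerated overloaded muscle (1.64). Pvalb was not highest on the normal array either (1.78, against 1.80 and 1.84 in these groups). A difference in fibre composition between the pools, from treatment, age or the muscles that entered each pool, may underlie the pattern as a hypothesis, and it was not tested.

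Tendon and cartilage genes were higher in regenerated overloaded muscle. Between-array scaling is argued against, since the list's median against regenerated muscle was at least 0.8528 under every scaling. Tendon tissue in the regenerated overloaded pool may contribute and could not be told from these values: 7 of 8 measured genes were higher there than on each of the other 3 arrays, Fmod at 4.25 relative to the array's 75th percentile, against 3.07 in regenerated muscle, but Scx at 3.70 against 3.69 in normal muscle. Kera was at -1.89, against -1.77 in normal and -1.66 in overloaded muscle. All 8 were above background in regenerated muscle too and no other list holds any of them. Neither point separates tendon tissue from a response of regenerated muscle to load, which stays open, untested.

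Genes higher on 1 array than on each of the other 3 were mostly read by probes printed once, 77.4% of 177. By array this was 83.3% on the normal, 78.3% on the regenerated, 97.4% on the overloaded and 57.1% on the regenerated overloaded array. The brightness of these probes does not account for the pooled 77.4%, as genes of matched brightness gave 53.1% (binomial SE at the baseline 3.70 points). The matched value was not computed for each array, and the 57.1% on the regenerated overloaded array lay near 53.1%. Single bright spots may therefore lie behind part of these genes, which the share on the regenerated overloaded array does not show for that array. High spots in the edge rows may lie behind part of the genes on the normal array. In 89.3% of 84 pairs of spots 2-fold apart there, the edge spot was the higher one. The edge spot was the higher one in 83.3%, 75.4% and 57.4% of such pairs on the regenerated, overloaded and regenerated overloaded arrays. A real difference in 1 pool stays open for any single gene and was not tested.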

How the results depend on the processing

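Leaving out the outer rows, leaving out probes printed once, and the smallest difference between spots were chosen after the data were seen. No paired analysis was made, as each group had 1 array and the labels do not say whether groups came from the same rats. No spot was saturated, so leaving out saturated probes removed nothing. Signal over background limits what can be read: without the filter on dim probes the counts were 2209 for regenerated against normal, 5698 for overloaded against normal, 1460 for regenerated overloaded against regenerated, 1438 for regenerated overloaded against overloaded muscle, and 5587 for the difference of differences, because probes at background enter. In the same order, normexp background correction with quantile normalization gave 116, 212, 102, 56 and 39, with 42 shared genes for overload and 12 for regeneration. Its offset of 50 draws dim signals together by construction, and how far this accounts for the fall was not tested. Without probes printed once the counts were 188, 334, 182, 121 and 71, as the calls on those probes were left out. In regenerated overloaded against overloaded muscle such probes read 59.0% of the calls, against 40.8% of the measured genes. At the smallest difference between spots, the first 4 counts were 88, 169, 92 and 48, by construction. With genes above background on both arrays compared, regenerated against normal gave 199, regenerated overloaded against regenerated 227 and regenerated overloaded against overloaded 144. On all 4 arrays 24 genes were shared for regeneration. These counts fell because genes above background on 1 array alone, with their at-least folds, were left out. At 1.5-fold, 513 genes were shared for overload and 235 for regeneration. The other 49 of 76 alternative counts lay within 1.5 times the count reported.

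Splits by direction moved with the scaling. Regenerated against normal muscle had 157 genes higher and 140 lower with the median of each array, and 322 and 91 with the authors' factor, against 212 and 112. Overloaded against normal muscle had 305 and 171, and 707 and 82, against 418 and 128. The difference of differences had 64 and 44, and 43 and 96, against 54 and 56. With cyclic loess it had 82 and 50, so the balance of directions there depends on the scaling. Without the outer rows the 5 counts were 272, 485, 325, 265 and 99. Against normal muscle the loss was mostly on the lower side. There, regenerated muscle had 201 genes higher and 71 lower, and overloaded muscle 400 higher and 85 lower. Of 696 list medians under 6 alternatives, 675 differed by less than the SD between the list's members and 20 by more. This SD is a wide limit, so a difference within it does not show that a median held. In overloaded against normal muscle the cell cycle median fell from 0.98 to 0.31 with normexp, within its SD of 0.76. The cell cycle list in regenerated against normal muscle, 0.36 as reported, was 0 with genes above background on 1 array at their smallest fold. Over the scalings, the sign changed for 23 of 54 medians inside the random lists and for 1 of 62 outside, the developmental sarcomere list in overloaded against normal muscle (-0.01 with the median of each array). Of named genes past 2-fold, none with a fold in the 4 alternatives run for genes changed direction there. Ppp1r42 in overloaded against normal muscle gave no fold with normexp, where its arrays differed by 0.06 and the sign had turned, nor did Cfap206 and Glp1r in regenerated overloaded against regenerated muscle with the mean over probes (-1.88 and 0.41, the latter turned). In all, 70 of 225 ended under 2-fold with normexp and quantile normalization, 16 of 224 with the mean over probes, 6 of 226 with quantile normalization and 4 of 226 with the authors' factor.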

Other observations

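No test was made for the values in this part. Cdkn2a and Cdkn2b, neighbouring genes that encode inhibitors of the cell cycle, were both higher in muscle that had regenerated, whether overloaded or not. Against normal muscle, regenerated muscle had at least 6.76-fold more Cdkn2a (3.18 with normexp) and at least 3.06-fold more Cdkn2b, and after overload the 2 genes were 4.89-fold (2.52 with normexp) and 3.65-fold higher in regenerated muscle. Cdkn2b was read from 10 spots and Cdkn2a from 2, and Cdkn2b ended under 2-fold with normexp in both (0.67 and 0.77 on the log2 scale) and with the mean over its probes in the first (0.65). Their log2 signals relative to the array's 75th percentile were -1.77 and -2.91 on the regenerated array and -1.99 and -2.75 on the regenerated overloaded array. Cdkn1c, another inhibitor of the cell cycle, was at 0.05 on the normal array and at 1.64, 2.02 and 1.99 on the regenerated, overloaded and regenerated overloaded arrays.

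Of the lists not described above, 6 had medians outside the random lists in regenerated overloaded against regenerated muscle. These were ribosome biogenesis (-0.22, percentile 0.06), heat shock (-0.23, percentile 0.335; between -0.29 and -0.13 over the scalings), satellite cell (-0.22, percentile 1.05; between -0.28 and -0.10), Schwann cell (-0.23, percentile 1.575; between -0.29 and -0.12), neutrophil and blood (0.31, percentile 99.6) and smooth muscle and pericyte genes (0.16, percentile 98.3; between 0.10 and 0.20). The Schwann cell median was also outside in regenerated overloaded against overloaded muscle (-0.22, percentile 1.06; between -0.26 and -0.05). Egr2, a transcription factor gene of myelinating cells in that list, was at least 3.07-fold higher in overloaded than in normal muscle and 1.54 higher on the log2 scale in regenerated overloaded than in regenerated muscle, and ended under 2-fold with normexp in both (0.66 and 0.80). No member of the other 5 lists passed 2-fold in any of the 4 comparisons. In the other comparisons the medians lay inside the random lists, between -0.12 and 0.13 for satellite cell, -0.25 and -0.04 for heat shock, -0.22 and 0.01 for ribosome biogenesis, -0.14 and 0.01 for Schwann cell, 0.08 and 0.12 for smooth muscle and 0.00 and 0.22 for neutrophil and blood genes.

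Inside the random lists in all 4 comparisons and without a member past 2-fold were the lists of neuromuscular junction and denervation genes (medians between -0.03 and 0.05), with Ncam1 at 0.79 and 0.95 in the 2 overload comparisons, of atrophy and autophagy (between -0.24 and -0.03), with Trim63, a ubiquitin ligase, at -0.96 and -0.67 there, and of endothelial genes (between -0.12 and 0.20). Overloaded muscle had Tnfrsf12a, a receptor of the load-responsive list (median -0.32, percentile 5.82), at -1.06, which was -0.95 with quantile normalization, -0.92 with normexp and -0.88 with the authors' factor. It had Igfbp4 (1.48, 1 spot) and Igfbp6 (1.001) of the IGF list (median 0.03) and Scd of the adipocyte list (median 0.02) at 1.64 against normal muscle.

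In regenerated against normal muscle the remaining medians lay inside the random lists and were -0.23 for oxidative phosphorylation, -0.21 for fatty acid oxidation, -0.20 for glycolysis, -0.16 for load-responsive, -0.06 for developmental sarcomere, -0.06 for tendon and cartilage, -0.06 for circadian and -0.07 for immediate early genes. The tendon and cartilage median was -0.17 in overloaded against normal muscle (percentile 29.2), and that of the IGF list -0.09 in regenerated overloaded against regenerated muscle (percentile 15.2). Between the 2 overloaded groups the medians of the IGF list (0.11, percentile 99.9; between 0.07 and 0.14 over the scalings) and of immediate early genes (-0.12, percentile 1.8) lay outside the random lists, and those of developmental sarcomere (0.05) and circadian genes (-0.03) inside. Over the scalings, the sign of the median changed for the load-responsive, heat shock, ribosome biogenesis, neutrophil, tendon, circadian, immediate early, developmental sarcomere and neuromuscular lists in regenerated against normal muscle. It changed for the IGF, adipocyte, Schwann cell, tendon and neuromuscular lists in overloaded against normal, for the endothelial and neuromuscular lists in regenerated overloaded against regenerated, and for the neuromuscular, load-responsive, atrophy and ribosome biogenesis lists in regenerated overloaded against overloaded muscle.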
